A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

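RNA from wild-type W303 yeast was measured on 8 two-colour Agilent arrays, 1 per time point from 5 to 40 min after release from alpha factor. Per the labels' protocols, log-phase cells in galactose medium were arrested with 240 nM alpha factor for 120 min, released into fresh medium and sampled every 5 min for 60 min; later times were not analysed here. RNA was isolated with an Ambion yeast kit and labelled with Agilent's two-colour Quick Amp kit, per the labels. Cy5 carried the 0 min RNA and Cy3 the time point on every array, so there was no dye swap. The labels name no separate cultures, and the samples were treated as successive drawings from the same culture.

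Per the file headers, the authors' scans were read with Agilent Feature Extraction 9.5.3.1, which gives for each spot the mean intensity and local background intensity in each channel on a linear scale. The same files hold a log10 ratio of Cy5 over Cy3 after Agilent's background subtraction, detrending and linear plus lowess dye normalization, per the file headers. The value file of the series that the authors deposited holds log10 values that follow this scanner ratio (r of at least 0.999999 on each array), so its direction is known. A correlation does not give the scale. The time-course fits with either set gave like log2 changes, however (RPL22B 1.269 with both, MF(ALPHA)1 0.861 and 0.862). The file's column medians were 0, 0, 0.00112, 0.00256, 0.00608, 0.00721, 0.000117 and 0 from 5 to 40 min. It was not centred beyond Agilent's normalization as far as these values show. It has 13045 entries against 13048 spots. Spot flags (well above background, saturated, outlier) were taken as deposited.

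Intensities were background-corrected with normexp (offset 50) and normalized within each array by loess with the 536 control spots at weight 0, in limma 3.58.1 under R 4.3.3 (data.table version 1.17.8). No scaling between arrays was applied. Outlier spots were left out, saturated spots were to be kept (there were 0), and the 2 spots of each probe were averaged. Ratios were turned to log2 of time point over 0 min. The array holds 6256 probes of 60 nt for genes; 5756 were matched by locus to a reference gene table of the yeast assembly and 500 kept the name in the file. The probe design predates that assembly, so no coordinates are given. For the gene with a second probe the brighter probe was kept, leaving 6255 genes. Genes well above background in at least 1 channel on at least 4 of the 8 arrays were tested (6169); 53 were never well above background. Median Cy3 signal per array ran from 2156 to 6858 and median Cy5 signal from 5656 to 6885, and the number of arrays sets the precision.

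The main test fitted each gene's 8 log2 ratios with a natural cubic spline of time with 3 degrees of freedom plus an intercept (4 residual degrees of freedom) and took limma's moderated F test of the spline terms, with Benjamini-Hochberg adjusted p under 0.05. The 0 min reference and dye bias drop out of these terms. A gene that passed rose or fell by the direction of the largest departure of its fitted curve from the fitted 5 min value. The median SE of the departures was 0.21. A model with an intercept only tested released against arrested cells with limma's moderated test. Genes 2-fold from 0 min on at least 2 consecutive arrays were counted without a test, and slopes were fitted with limma within each row of arrays on the slide (4 arrays each).

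Before the data were examined, 22 gene lists were fixed: G1/S, histone, S/G2, G2/M, M/G1, MCM/ECB, pheromone response, alpha-cell, meiosis, galactose, ribosomal protein, ribosome biogenesis, stress response, respiration, glycolysis, methionine and sulphur, phosphate, amino acid synthesis, cell wall and bud growth, reference, silent and subtelomeric, and mitochondrial genome genes. The share of time-dependent genes in each list was set against all other tested genes by Fisher's exact test, two-sided, adjusted over the 22 lists. List medians per array were placed among 10000 random lists of the same size matched on intensity in 10 bins. CHS1, FAR1, FBA1, KIP2, PGM2, PHM8 and TPI1 are each in 2 lists. A further 9 lists were chosen after the data were seen and are given only in the closing part.

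Named genes followed a rule fixed at the same time: 16 anchors; the 8 largest rises and 8 largest falls among called genes measured in both channels on all arrays; the 6 highest and 6 lowest means after release with the same sign on all arrays; up to 3 called members of each list with the largest departure, or, if none passed, the 2 with the largest mean absolute ratio; and the highest and lowest gene at each time. It named 84 entries. Genes outside the rule, such as exceptions in a list or the members of short lists, were chosen after their values were seen.

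The time-course test was checked on simulated data with 200 of 6169 genes changed by a steady ramp: it recovered 0% at 0.5 and 1 log2, 54% at 2 and 78% at 3, with 0% false calls. The test of released against arrested cells recovered 80% at 0.5 and 100% at 1 or more, with 2.06% false calls. The slope test over 5 to 20 min recovered 16%, 80%, 96% and 98% of changes of 1, 2, 4 and 6 log2, and that over 25 to 40 min 2%, 42%, 82% and 98%. With 200 changed genes the adjusted threshold is stricter than in the data, where 1755 were called. Noise was independent over genes, with the fitted scatter scaled again by array. The simulated released test had no dye bias and no error in the 0 min RNA. These rates thus describe the simulated setting and not the real tests.

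Alternatives were no background subtraction, Agilent's ratios, the deposited table, median centring in place of loess, scaling between arrays, no filter or a stricter filter on dim probes, the mean of probes, a quadratic or straight line in place of the spline, a step term for the slide row, an intensity trend in limma's prior, the spread around the curve for the mean test, a 1.5-fold threshold, a 2-fold limit added to the adjusted p, and each time point left out in turn. Leaving out both the 25 and 30 min arrays and weighting arrays with limma were chosen after seeing the data. The labels give no paired replicates. Control spots were left out of all tests and are described in the closing part.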

Results

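Budding yeast (Saccharomyces cerevisiae, strain W303, wild type per the labels) grew in galactose medium, were held in G1 with alpha factor, the mating pheromone of alpha cells, and were then moved to fresh galactose medium without it. RNA drawn at 5, 10, 15, 20, 25, 30, 35 and 40 min after release was compared with RNA drawn at 0 min, and the series title states the purpose as a synchronised cell cycle time course in galactose. There was 1 array per time point, 8 in all, on 1 slide. None of these arrays held cells moved to fresh medium with alpha factor kept. Effects of its removal and of the fresh medium thus cannot be told apart here. The time point carried Cy3 and the 0 min RNA carried Cy5 on all 8. Ratios are given as log2 of time point over 0 min, so a positive value means a higher level after release; the log10 ratios the authors deposited run the opposite way. Of 6255 genes, 6169 had signal enough to be tested and 5950 were well above background in both channels on all 8 arrays.

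The median Cy3 signal of the arrays was between 4539 and 6858, except at 25 min (2156) and 30 min (2580), while the Cy5 signal of the shared 0 min RNA stayed between 5656 and 6885. The residual scatter around the fitted curves was also largest on those arrays, with SDs of 0.30 at 25 min and 0.29 at 30 min against 0.11 to 0.21 on the other 6. Between 95.5% and 98.5% of gene probes were well above background in Cy3, and no spot was saturated. The number of arrays limits the precision: no time point could be tested on its own, and because the labels name no separate cultures and the 8 samples were treated as drawings from the same culture, p-values measure the scatter within this experiment, which may be technical. The lowest correlation between any pair of arrays over genes was 0.18.

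**Figure D1:**
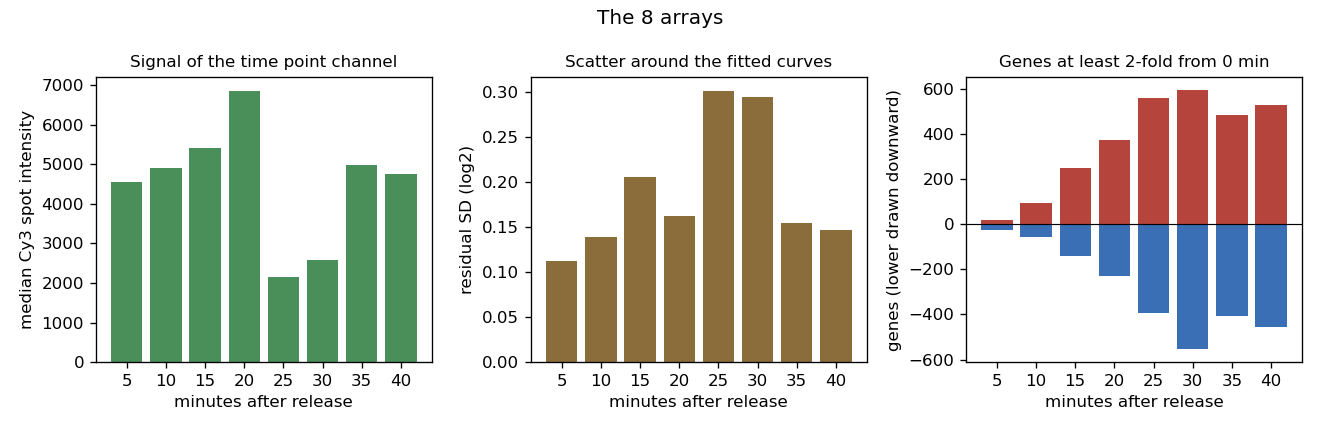
Bar charts with the 8 arrays on the x axis in minutes after release: median Cy3 spot intensity, residual SD (log2) around the fitted curves, and the number of genes at least 2-fold higher (upward bars) or lower (downward bars) than at 0 min. The 25 and 30 min arrays have the weakest Cy3 signal, 2156 and 2580, and the largest scatter, 0.30 and 0.29.

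The first comparison asked which transcripts changed over the 40 min after release. Most G1/S, histone, S/G2 and ribosome biogenesis genes rose, and most pheromone response, stress response, and methionine and sulphur genes fell. The gene with the largest rise was TOS4, which encodes a forkhead-associated domain protein, by 5.63 ± 0.15 (fitted departure from 5 min ± SE, 8 arrays; adjusted p = 7.76e-06). It was followed by the S-phase cyclin gene CLB6 (5.58 ± 0.50), the cohesin subunit gene MCD1 (5.30 ± 0.15), CSI2 (5.25 ± 0.19), the Pho85 cyclin gene PCL1 (4.78 ± 0.27), SVS1 (4.52 ± 0.15), the histone H2B gene HTB2 (4.49 ± 0.21) and the G1 cyclin gene CLN1 (4.27 ± 0.14). The largest falls were those of STR3, a cystathionine beta-lyase gene of methionine synthesis (-4.72 ± 0.25), the mating genes FIG1 (-4.33 ± 0.28) and FIG2 (-4.11 ± 0.28), the aldehyde dehydrogenase gene ALD6 (-4.21 ± 0.32), the methionine permease gene MUP1 (-3.68 ± 0.46), FMP48 (-3.66 ± 0.24), the a-specific gene ASG7 (-3.65 ± 0.30) and the amino acid permease gene AGP1 (-3.50 ± 0.44). In all, 1755 genes, 28.4% of those tested, were time-dependent in limma's spline test after Benjamini-Hochberg adjustment: 899 rose and 856 fell, 654 and 537 of them by at least 2-fold. Position on the slide ran with time, 5 to 20 min in the first row of arrays and 25 to 40 min in the second, and with a step term for the row 302 genes rose and 164 fell. The counts also depended on single arrays: 307 rose and 304 fell without the 5 min array, 563 and 451 without 10 min, 548 fell without 35 min and 474 fell without 40 min. Of the 1755 genes, 1722, 1751, 1753 and 1745 kept the sign of their departure without 5, 10, 35 and 40 min. A fit without 1 array has fewer residual degrees of freedom, so a call can be lost without a change of direction. These fits share the remaining arrays, so the like signs are no independent check. Among the genes named here, CLB2, CLB6, SPO12, GAL3, GCY1, PGM2, TEC1, SPO11, SPR3, PHM8, SPL2, TUB2, CIT1, SDH1, SDH2, RPL22B, RPS9A, ARX1, RRP36 and PRM6, 20 in all, kept their direction but lost the call without the 5 min array, 10 did without 10 min and 8 without 40 min. The step term for the row cost 27 named genes their call, though all 27 kept their direction: AGP1 stood at -3.89, DCS2 -2.92, MET14 -2.35, FAR1 -1.72, IME1 -0.64 and TUB2 0.90. Of the 1755 genes, 1725 had departures of the same sign with that term. A straight line cost 12 their call without a change of direction, among them PCL1 (adjusted p = 0.0585), CLB5 (0.0648), CLB6 (0.155), MUP1 (0.293) and SWI5 (0.0517), and CDC6 lost it and turned (-1.21, adjusted p = 0.357). Scaling the arrays to equal spread, which also takes out a response that grows with time, cost 15 their call without a change of direction. With that scaling CIT1 lost it and turned, and CDC20, TEC1 and FAR1 were called as rising in place of falling (adjusted p = 0.0260, 0.00655 and 0.0234).

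Late G1 genes were followed as targets of the transcription factors SBF and MBF. RNR1, the large subunit of ribonucleotide reductase, went from a log2 ratio of 1.22 at 5 min to 5.74 at 25 min, a fitted rise of 4.25 ± 0.22 (adjusted p = 6.56e-05). POL1, the catalytic subunit of DNA polymerase alpha, rose by 4.18 ± 0.20, the S-phase cyclin gene CLB5 by 3.38 ± 0.15 and the G1 cyclin gene CLN2 by 2.26 ± 0.15. Of the 59 G1/S genes tested, 57 rose and 0 fell (59 and 0 adjusted over the list alone), against 27.8% of other genes called in either direction (Fisher's exact test, two-sided, adjusted p = 7.83e-28 over 22 lists). RNR3 (0.50 ± 0.17) and HCM1 (2.44 ± 0.70) did not pass over all genes; they are named because they are the exceptions. The list median was 0.30 at 5 min and 3.07 at 25 min, above all 10000 intensity-matched random lists on each of the 8 arrays. With the step term for slide row 53 members rose. With arrays scaled to equal spread the RNR1 departure was 2.69 and missed the threshold (adjusted p = 0.0567). Members of this and the other lists are co-regulated, so each list's p describes the list in this experiment.

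The replication licensing genes and targets of the early cell cycle box rose early, and their list median came back to near its start by 40 min. It was 0.14 at 5 min, 1.22 at 20 min and 0.11 at 40 min. Of the 14 MCM/ECB genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 2.20e-06). The largest rises were those of the repressor gene YHP1 (3.37 ± 0.23) and of CDC6, which loads the MCM helicase (2.57 ± 0.32, largest at 15 min); FAR1, the Cdc28 inhibitor of the pheromone arrest, fell (-1.70 ± 0.33), but was called as rising (0.80) with arrays scaled to equal spread. With the row term 9 members rose and 1 fell, and with a straight line 2 rose. Without the 40 min array 1 member fell, and without the 5 min array 3 rose and 6 fell. In the latter fit CDC6 was called as falling (-1.89, adjusted p = 0.00839), because the departure is then measured from 10 min. With a quadratic CDC6 lost the call and turned (-1.21, adjusted p = 0.173).

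Histone genes rose, and most of the rise in their list median came after 15 min. It was -0.02 at 15 min, 1.37 at 30 min and 2.35 at 40 min, and all 9 rose (9 adjusted over the list alone; adjusted p = 2.79e-05). HTB2 and HTA2 rose by 4.49 ± 0.21 and 4.09 ± 0.35, HHF2 by 3.03 ± 0.18, HTB1 by 2.68 ± 0.49 and HTA1 by 2.10 ± 0.36. Over 5 to 20 min the slope test called 3 histone genes as rising and 1 as falling, and HTB2 stood at 2.41 and HTA2 at 1.85 by 20 min. Over 25 to 40 min it called 0 histone genes, but it called 0 of all tested genes there. The median histone slope was 0.48 log2 per 10 min in the first span and 1.51 in the second. Slopes were positive for 7 and 9 of the 9 genes. The core histone genes come in near-identical pairs whose probes can share signal. With arrays scaled to equal spread, the HTB1 departure was 2.21 and missed the threshold (adjusted p = 0.0506).

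Spindle, kinetochore and other genes known to peak between S phase and G2 mostly rose. Of the 31 S/G2 genes, 23 rose and 2 fell (25 and 2 adjusted over the list alone; adjusted p = 9.70e-09). DUO1 of the DASH complex (3.11 ± 0.23), the gamma-tubulin complex gene SPC97 (3.08 ± 0.36) and SLK19 (2.70 ± 0.16) had the largest rises; the members that fell were HST4 (-1.88) and CIK1 (-0.51), named because they went the other way. Counts were 13 risers without the 5 min array and 11 with the row term, and 1 of the 2 falls was lost without the 5, 10, 15, 20, 35 or 40 min array. With the row term 0 fell. With Agilent's ratios, the deposited table, median centring, scaling between arrays, a quadratic or a straight line 1 fell.

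Mitotic genes showed no common direction by 40 min. Among 31 G2/M genes, 8 rose and 6 fell (11 and 9 adjusted over the list alone), a share that did not pass the list test (adjusted p = 0.0778). SWI5, a transcription factor of late mitosis, rose by 1.31 ± 0.21 with its highest ratio, 1.35, at 40 min, and the septin-binding protein gene BNI5 rose by 1.94 ± 0.15. The mitotic cyclin gene CLB2 fell (-1.30 ± 0.23, lowest fitted value at 25 min), as did CDC20, the activator of the anaphase-promoting complex (-0.55 ± 0.18), and SPO12 (-1.44 ± 0.22). The CLB2 probe was far brighter, with a mean log2 intensity of 16.2 against 9.5 for SWI5, 9.8 for SPO12 and 10.8 for CDC20. Actin (ACT1) stood at 16.5. Why CLB2 was so bright was not tested, so its fall is to be read with caution. SWI5 (0.47) and CDC20 (-0.47) lost the call without the 40 min array, CDC20 also without 35 min (-0.52), and the CLB2 departure was -1.19 and missed the threshold without 5 min (adjusted p = 0.0614). G2/M genes that rose numbered 4, 5 and 1 without 5, 35 and 40 min, and those that fell 2 and 3 without 5 and 40 min. With the row term 4 rose and 1 fell, the CDC20 and SPO12 departures missing the threshold (-0.54 and -1.65, adjusted p = 0.165 and 0.0906), and with a quadratic 4 rose and 10 fell. CDC20 was called as rising (0.47) with arrays scaled to equal spread. Of 20 M/G1 genes, 3 rose and 7 fell, the same counts adjusted over the list alone (adjusted p = 0.0778): RME1 (-2.49 ± 0.19) and TEC1 (-1.60 ± 0.19) fell and BUD9 rose (2.30 ± 0.17). With arrays scaled to equal spread the balance turned, as 6 rose, TEC1 (0.89) among them, and 2 fell, and with the row term 2 rose and 2 fell. Of the M/G1 genes 1 rose without 5 min, and 4, 3, 4 and 3 fell without 5, 10, 35 and 40 min. The Cdk inhibitor gene SIC1 did not pass (-0.88 ± 0.27, adjusted p = 0.105).

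**Figure D2:**
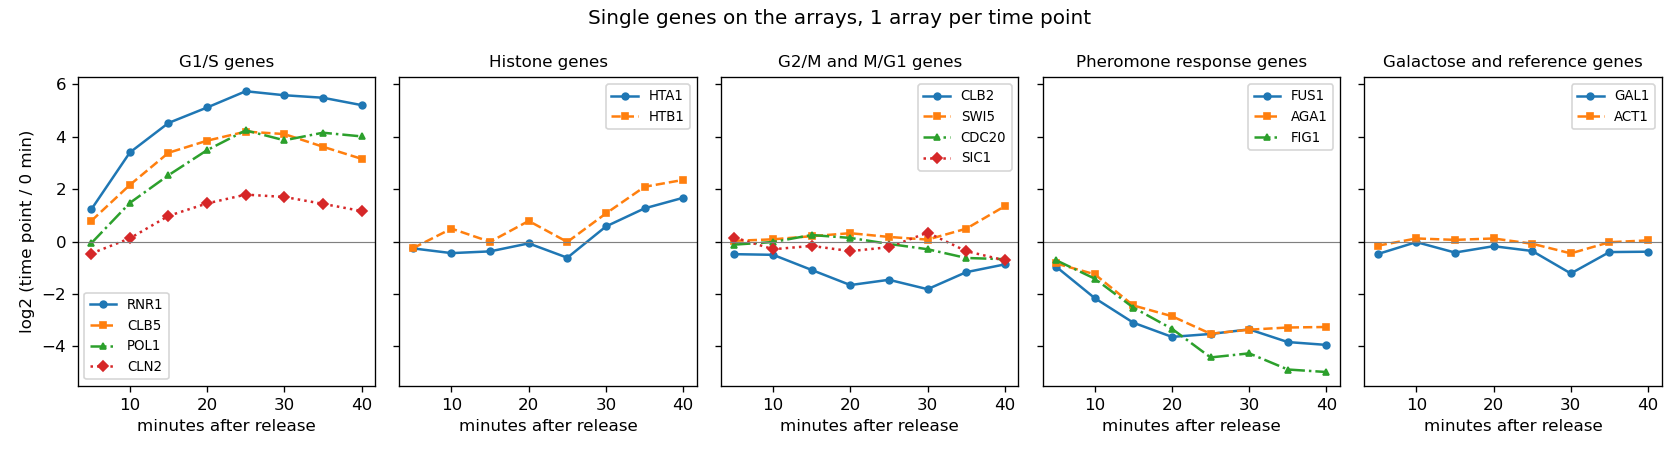
Log2 ratio of time point over 0 min (y axis) against minutes after release (x axis) for single genes in 5 panels, with 1 array per point and no error bars. RNR1 reaches 5.74 at 25 min, HTB1 reaches 2.35 at 40 min, FIG1 reaches -4.98 at 40 min, and ACT1 lies between -0.45 and 0.12.

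Genes induced by mating pheromone through the factor Ste12 fell after release. FUS1, needed for cell fusion, was at -0.96 at 5 min and -3.95 at 40 min, with a fitted departure of -3.07 ± 0.20. FIG1 (-4.33 ± 0.28) and AGA1, the anchor of the mating agglutinin (-2.77 ± 0.21), fell too. Of 34 pheromone response genes, 26 fell and 1 rose (27 and 2 adjusted over the list alone; adjusted p = 5.10e-09). The member that rose, GIC2 (2.05), encodes an effector of Cdc42 in bud growth; it is named because it was the only riser. The list median went from -0.57 at 5 min to -2.53 at 40 min and lay below all 10000 random lists on every array. With the row term 14 members fell, and with arrays scaled to equal spread 15 fell and 5 rose; 2 rose without the 25 or the 30 min array.

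BAR1, the protease that degrades alpha factor, was not well above background in either channel on any of the 8 arrays, so no ratio is given. Its median signal was 59.4 in Cy3 and 53.4 in Cy5, beside 61.0 and 54.8 for negative control spots. The strain was labelled wild type.

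Ribosome biogenesis genes rose together while ribosomal protein genes mostly did not pass the test. Of 72 biogenesis genes, 64 rose and 0 fell (68 and 0 adjusted over the list alone; adjusted p = 5.13e-26), with a list median of -0.16 at 5 min and 0.95 at 25 min. The shuttling factor gene ARX1 rose by 2.02 ± 0.32, RRP36 by 1.83 ± 0.34 and LTV1 by 1.76 ± 0.29. Of 138 genes taken in by ribosomal protein names, 5 rose and 0 fell (1 and 0 adjusted over the list alone), 3.62% against 29.0% of other genes (adjusted p = 2.88e-13, fewer than the rest). They were RPP1 (1.81 ± 0.22), RPS9A (1.51 ± 0.24), RPL22B (1.26 ± 0.34), RPS27A (1.04) and RPL18B (0.86); RPP1 encodes a subunit of RNase P and no ribosomal protein, and many of the others have near-identical copies. RPL22B passed narrowly (adjusted p = 0.0492) and lost the call with Agilent's ratios, the deposited table, median centring, no dim filter or the intensity trend, and without 5, 10, 15, 20, 35 or 40 min; its departure was 0.92 without 5 min and at least 1.16 in the others. Biogenesis genes that rose numbered 15 without the 5 min array and 18 with the row term; ribosomal protein genes that rose numbered 1 without 5 min, 2 without 40 min, 9 without 25 min and 0 with the row term. ARX1 (2.14), RRP36 (2.17), LTV1 (1.07), RPP1 (1.81), RPS9A (1.66) and RPL22B (2.34) lost the call with that term, and only LTV1 had a smaller departure.

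Genes of the general stress response fell. The largest falls were those of SPI1 (-2.85 ± 0.28), the trehalose phosphatase gene TPS2 (-2.63 ± 0.20) and DCS2 (-2.51 ± 0.30). Of 35 members, 26 fell and 0 rose (27 and 0 adjusted over the list alone; adjusted p = 7.25e-08); the list median was 0.16 at 5 min and -1.02 at 40 min. Without the 5 min array 17 fell, and with the row term 7 did.

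Methionine and sulphur genes fell. STR3, MUP1 and the adenylylsulphate kinase gene MET14 (-3.13 ± 0.39) led the list, of which 20 of 23 members fell and 0 rose (21 and 0 adjusted over the list alone; adjusted p = 2.83e-08). MET13, MET8 and MET22 did not pass (-0.85, -0.47 and -0.59). The list median was -0.17 at 5 min and -1.91 at 30 min, and 10 members fell with the row term.

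**Figure D3:**
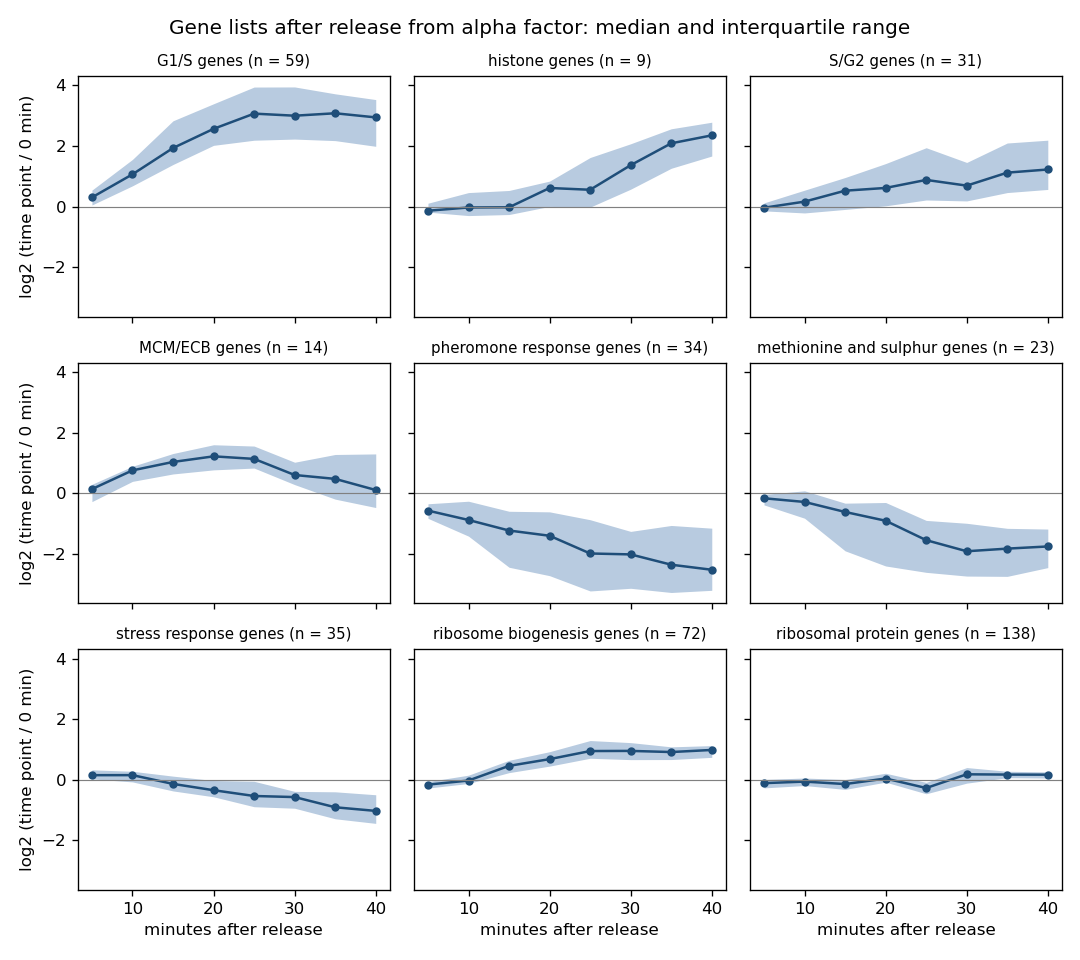
Median log2 ratio of time point over 0 min (line, y axis) and interquartile range over genes (shaded) of 9 gene lists against minutes after release (x axis), 1 array per point. The G1/S median reaches 3.08 at 35 min, the histone median 2.35 at 40 min and the pheromone response median -2.53 at 40 min. The ribosomal protein median stays between -0.27 and 0.18.

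Other metabolic lists did not differ from the rest of the genes in their share of calls, a test that takes no account of direction. By the mean after release, 27 of 43 respiration genes were lower and 0 higher, and 9 of 13 galactose genes lower and 1 higher. Of all 6169 genes 1644 were lower and 1699 higher. The respiration median stood at percentiles 19.4, 0 and 0.695 of the matched random lists at 5, 25 and 40 min. With the row term 0 respiration, 0 galactose and 0 amino acid synthesis genes fell. CIT1, SDH1, SDH2, GCY1, PGM2, SER33, ARG4 and HOM3 lost the call with that term but kept their direction, with departures of -1.23, -1.57, -0.80, -0.61, -0.58, -1.33, -1.21 and -0.82, as did GAL3, whose departure was larger than without it. Of 43 genes of the citric acid cycle and oxidative phosphorylation, 8 fell and 0 rose (0 and 0 adjusted over the list alone; adjusted p = 0.25); citrate synthase CIT1 (-0.98 ± 0.22) and the succinate dehydrogenase genes SDH1 and SDH2 (-0.95 ± 0.18 each) were the largest. With median centring 4 respiration genes fell, with a straight line 3, and with arrays scaled to equal spread 1 fell, 1 rose and CIT1 stood at 0.23. Of the respiration genes 0 fell without 5 or 10 min, 4 without 15 min, 2 without 20 or 40 min and 3 without 35 min. Of 18 glycolysis genes, 1 fell, the hexokinase gene HXK1 (-1.80 ± 0.19; 1 over the list alone; adjusted p = 0.0675). Among 13 galactose genes 3 fell: GCY1 (-1.42 ± 0.23), PGM2 (-0.96 ± 0.18) and GAL3 (-0.96 ± 0.14), 3 adjusted over the list alone (adjusted p = 1), and 0 did without the 5 min array. The galactokinase gene GAL1 did not pass (-0.35 ± 0.29, adjusted p = 0.333), and stood at 0.38 with median centring. Amino acid synthesis genes gave 11 that fell, led by SER33 (-1.58 ± 0.22), ARG4 (-1.38 ± 0.13) and HOM3 (-1.33 ± 0.21), and 1 that rose, CPA1 (0.52), of 41 (11 and 1 adjusted over the list alone; adjusted p = 0.95); 6, 7 and 5 fell without 5, 10 and 40 min, and 0 rose without 5, 10, 15, 20, 35 or 40 min. Of 16 phosphate genes 4 fell: PHM8 (-1.34 ± 0.27), SPL2 (-1.28 ± 0.16), GPP2 (-0.96 ± 0.15) and PHM6 (-0.59), 4 adjusted over the list alone (adjusted p = 1), and 1, 2 and 2 fell without 5, 35 and 40 min and 1 with the row term. Of 37 cell wall and bud growth genes, 11 rose and 3 fell, the same counts adjusted over the list alone (adjusted p = 0.25); CIS3 (3.44 ± 0.33), the Cdc42 effector gene GIC1 (3.21 ± 0.21) and MSB2 (2.57 ± 0.25) rose; 7 rose without 5 min, and 5 rose and 0 fell with the row term.

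Markers of cells that the culture should not hold were mostly not called as changing over time. This does not show that their transcripts were absent, because the test asks only about change. All 6 alpha-cell and all 18 meiosis genes had signal enough to be tested. Of 6 alpha-cell genes 0 were called in limma (0 adjusted over the list alone; 1 at an unadjusted p under 0.05; adjusted p = 0.25), though 1 rose and 1 fell without 25 min, and likewise without 30 min. The alpha pheromone gene MF(ALPHA)1 was called as rising with Agilent's ratios (0.86, adjusted p = 0.0427), the deposited table (adjusted p = 0.0424), median centring (0.0428) and scaling between arrays (0.0444). As reported it had a departure of 0.62 ± 0.24 and MATALPHA2, whose probe shares sequence with a second copy, -0.98 ± 0.31. Of 18 meiosis genes 3 fell, IME1 (-1.22 ± 0.22), SPO11 (-0.95 ± 0.16) and SPR3 (-0.78 ± 0.14), 3 adjusted over the list alone (adjusted p = 0.5), with 1 left without 5 min and 0 without 10 min or with the row term. Of 15 reference genes, 1 rose, the beta-tubulin gene TUB2 (1.12 ± 0.19; 1 over the list alone; adjusted p = 0.13; 0 without 5 or 40 min or with the row term), and the actin gene ACT1 did not pass (0.32 ± 0.19, adjusted p = 0.247). Of 35 seripauperin and COS genes limma called 0 (0 adjusted over the list alone; 0 at an unadjusted p under 0.05; adjusted p = 2.79e-05, fewer than the rest); many have near-identical copies, and COS10 and COS111 had departures of 0.67 ± 0.54 and 0.16 ± 0.33. By the mean after release 27 of these 35 genes were lower and 0 higher. Their median stood at percentiles 56.7, 0.02 and 0.34 of the matched random lists at 10, 30 and 40 min. The 0 calls thus do not show that the family stayed at its 0 min level. The 6 genes of the mitochondrial genome gave 0 calls in limma (0 adjusted over the list alone; 1 at an unadjusted p under 0.05; adjusted p = 0.25), with OLI1 at -1.48 ± 0.67 and COX1 at 0.73 ± 0.53. Their list median swung between arrays, at -0.50, -0.12, -0.79, -0.14, -1.19, -0.70, 0.05 and 0.04 from 5 to 40 min. A smooth curve takes such swings as scatter, so the 0 calls do not show stable levels. Leaving out the 25 min array added 1 rising mitochondrial gene, 1 falling gene of the seripauperin and COS families, 1 rising and 1 more falling glycolysis gene, and 2 rising galactose genes. Leaving out 30 min gave 1 rising galactose gene and 1 rising meiosis gene, 2 reference genes rose without 15, 25 or 30 min, 1 phosphate gene rose without 5, 25 or 30 min, and 1 stress response gene rose without 15 min.

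The second comparison set all released samples against the arrested cells. PCL1 was highest, with a mean log2 ratio of 5.41 ± 0.49 (SE, 8 arrays) and a positive ratio on 8 of 8 arrays (adjusted p = 0.000127). MCD1 (4.62 ± 0.57), CLB6 (4.61 ± 0.56), RNR1 (4.53 ± 0.46), TOS4 (4.42 ± 0.62) and the homeobox repressor gene YOX1 (4.31 ± 0.38) followed. FIG2 (-3.41 ± 0.48), FIG1 (-3.32 ± 0.48), MUP1 (-3.14 ± 0.41), FUS1 (-3.07 ± 0.31), RGI1 (-2.95 ± 0.31) and STR3 (-2.91 ± 0.52) were lowest, each negative on 8 of 8 arrays. By limma's test of the mean against 0, 1699 genes were higher and 1644 lower after release, 255 and 182 of them by at least 2-fold. Of the G1/S genes 56 of 59 were higher and of the pheromone response genes 31 of 34 were lower, and GAL1 was lower (-0.43 ± 0.11, adjusted p = 0.0104). This test leaves out the spread of the 0 min RNA itself, and without a dye swap it contains each probe's dye bias. The 8 arrays are successive time points and not replicates. A gene's change over time counts as spread, so these SEs hold its time course as well as error.

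Described array by array, with no test, more genes stood at least 2-fold from 0 min late than early. At 5 min 16 were higher and 26 lower, at 20 min 370 and 232, and at 40 min 527 and 455. PCL1 was the highest gene at 5, 10, 15, 25 and 30 min, CLB6 at 20 min and TOS4 at 35 and 40 min. The lowest were the polyamine exporter gene TPO2 at 5 min (-1.77), PRM6 at 10 min (-2.57), MUP1 at 15, 20 and 30 min, FIG2 at 25 min and FIG1 at 35 and 40 min. On at least 2 consecutive arrays 576 genes were 2-fold higher and 461 were 2-fold lower.

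The time at which each list was farthest from its start is described here, with no test between lists. The median time of the largest departure among called members was 25 min for MCM/ECB genes, 30 min for G1/S and ribosome biogenesis genes, and 40 min for histone, S/G2 and pheromone response genes. Over all called genes, 337 risers were farthest from 5 min at 30 min and 341 at 40 min, and 232 and 451 of the genes that fell. The arrays analysed here ended at 40 min, so an extreme at 40 min may lie later. The G1/S time was 25 min without the 30 min array, the histone time was 35 min without the 40 min array, and the MCM/ECB time was 40 min without the 5 min array. With arrays scaled to equal spread the pheromone, G1/S and MCM/ECB times were 20, 20 and 15 min, with the row term the pheromone time was 30 min, and with a straight line the G1/S, biogenesis and MCM/ECB times were 40 min.

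Trends were also taken within each row of arrays on the slide, which leaves out any difference between rows. Over 5 to 20 min, 811 genes rose and 682 fell by limma's slope test, among them 57 G1/S genes, 53 ribosome biogenesis genes and 12 MCM/ECB genes rising and 22 pheromone response, 14 methionine and sulphur and 13 stress response genes falling. The 4 arrays of 25 to 40 min gave 0 rising and 0 falling genes in limma, where 329 and 382 had an unadjusted p under 0.05; 8 of 9 histone genes were among the former. The first counts were 906 and 760 with median centring, 683 and 683 with Agilent's ratios, and 1 and 1 with arrays scaled to equal spread; the SD over genes grew from 0.27 at 5 min to 0.69 at 20 min, and that scaling removes such growth whatever its cause. They were 201 and 120 without the 5 min array and 370 and 161 without 20 min. Leaving out the 25 min array gave 717 rising and 621 falling genes over the second span, leaving out 30 min gave 654 and 767, and leaving out 40 min gave 9 and 10. Without 25 or 30 min few arrays remain. The span then begins at the other array with large scatter (residual SD 0.29 at 30 min, 0.30 at 25 min). These calls may come from that array and do not show that trends were unmasked.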

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

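The test on a-specific genes was chosen after the result was seen; the other tests in this part were not.

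Control spots were outside the main measurement. All 10 spike-in control probes for adenovirus E1A RNA were above the highest negative control spot (309.7 in Cy3, 452.9 in Cy5) in both channels on all 8 arrays. Their median log2 ratios ran from -4.93 to 1.97. After normalization all 10 had their lowest ratio at 30 min, at a median of -1.30 from each probe's own median, and 9 had their second lowest at 25 min.

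The 25 and 30 min arrays scattered more around the fitted curves than the other arrays. Dim spots alone would leave the brightest genes unaffected. In the brightest 1234 genes, of 5 groups by brightness, the residual spread was 1.87 times that of the other arrays (95% interval over genes 1.75 to 1.98). This argues against dim spots as the whole cause. Genes on the same array are not independent replicates, so the interval leaves out the error of the 25 and 30 min arrays themselves. The departure of these arrays from the line between 20 and 35 min followed coding length over 5717 genes, with Spearman correlations of 0.32 at 25 min and -0.357 at 30 min, so a difference in RNA integrity or labelling that depends on length may contribute, in opposite directions on the arrays. Probe GC content stays open, with correlations of 0.152 at 25 min and only 0.028 at 30 min. A short change in the cells stays open too. The deviations of the arrays correlated at 0.246 over genes, but both were taken from the same line. That correlates them without any change in the cells, so this value does not test such a change.

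BAR1 was not well above background on any array. Low expression of a-specific genes in this culture is excluded as the cause, since 6 of 6 other a-specific genes (STE2, STE6, MFA1, MFA2, ASG7 and AGA2) were well above background in both channels on all 8 arrays. A strain change at the locus or a failed probe may account for it, and no value here tells these apart; strains that lack BAR1 are commonly used for alpha factor arrest, but the labels say wild type.

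Ribosomal protein genes stayed near 0 while ribosome biogenesis genes rose. They did share a small shift: 39 of 138 were above 0 at 5 min (median -0.11) and 112 at 40 min (0.17). These medians stood at percentiles 0 and 100 of the matched random lists. Without the 25 and 30 min arrays 12 rose against 5 as reported, while all calls went from 1755 to 2390. The scatter of those arrays may thus cost calls. With median centring in place of loess the ribosomal protein median at 40 min was 0.0768 (interval over genes 0.0439 to 0.123). This argues against loess pulling bright genes to 0. Compression of bright spots is also argued against. The departures of 678 other genes as bright were spread 0.944 times as widely as those of all other genes (interval over genes 0.889 to 1.02). Of the 678 genes, 28.9% were called against 3.62% of ribosomal protein genes. Genes on the same arrays are not independent replicates, so both intervals leave out the error of the arrays themselves. The 678 genes were matched on brightness and not on coding length, which the deviations of the 25 and 30 min arrays followed. The ribosomal protein median was 0.05 at 20 min, -0.27 at 25 min and 0.18 at 30 min. A part of coding length in the low number of calls was not tested and stays open. No biological explanation was tested.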

How the results depend on the processing

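The alternatives were planned, except leaving out the 25 and 30 min arrays and the array weights, which were chosen after seeing the data; limma's array weights did not converge. Between 9 and 13 lists differed from the rest, against 10 as reported. Between 1393 and 1914 genes were time-dependent under the other background, normalization, filter and curve settings, of which 1162 (scaling between arrays) to 1753 (mean of probes) were shared with the 1755. The share that rose was 49.2% to 54.1% under other scalings, 51.2% as reported and 64.8% with the row term. Signal over background limits 53 genes to no measurement. Where a departure turned, the cause was not tested, except that without the 5 min array departures start at 10 min.

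With median centring GAL1 was at 0.38. With scaling between arrays the G1/S, pheromone and MCM/ECB extremes came at 20, 20 and 15 min, CDC20 was at 0.47, GAL1 0.61, TEC1 0.89, FAR1 0.80 and CIT1 0.23, 292 genes were 2-fold lower on consecutive arrays, and 1 gene rose and 1 fell within 5 to 20 min. With a quadratic ACT1 was at -0.087, CDC6 -1.21 and COS10 -0.56. With a straight line the G1/S, biogenesis and MCM/ECB extremes came at 40 min, ACT1 was at -0.087, MF(ALPHA)1 -0.29, CDC6 -1.21 and COS10 -0.56. With the row term 302 rose and 164 fell, the pheromone extreme came at 30 min, and OLI1 was at 2.60, COS10 -1.94 and COS111 -1.51. Without 25 and 30 min the G1/S extreme came at 35 min, GAL1 was at 0.17, and 1678 of 2390 calls were shared with the 1755. With array weights COS111 was at -0.57. A 2-fold limit left 537 that fell, and a 1.5-fold threshold gave 1186 higher and 1148 lower on consecutive arrays.

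Leaving out each time point in turn gave 307 to 1214 genes that rose and 304 to 1140 that fell, 201 to 1049 rising and 120 to 916 falling within 5 to 20 min, and 0 to 717 rising and 0 to 767 falling within 25 to 40 min. The extreme ranged from 25 to 30 min for G1/S genes, 35 to 40 for histone genes and 20 to 40 for MCM/ECB genes. Departures ranged from -0.65 to 0.44 for GAL1, -0.50 to 0.73 for MF(ALPHA)1, -0.35 to 0.35 for ACT1, -0.72 to 0.73 for COS10, -1.89 to 2.64 for CDC6 and -0.62 to 0.92 for COX1.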

Other observations

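The 9 lists in this part were chosen after the data were seen, and the tests of time order and of neighbouring genes were not. The p-values of these 9 lists come from the data that led to the choice. Passing or missing the threshold is thus a description of a list and not a test of it.

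Further groups moved with the series. Of 19 cohesion and condensin genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 6.33e-05 over 9 lists), led by MCD1 (5.30) and the cohesin maintenance gene PDS5 (3.62); several are G1/S genes of the earlier list. Subunits of RNA polymerases I and III gave 14 risers of 21 and 0 that fell (18 and 0 adjusted over the list alone; adjusted p = 0.000905), among them RPA135 (1.72). Of 22 amino acid permease genes 11 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 0.0486), with AGP1 (-3.50), DIP5 (-3.31) and GAP1 (-2.53); MUP1, MUP3 and MMP1 are also in the methionine list. Hexose transporter genes gave 9 that fell of 16 (10 adjusted over the list alone; adjusted p = 0.0408), of which HXT6 and HXT7 are near-identical.

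Proteasome genes gave 0 calls of 31 in limma (0 adjusted over the list alone; 0 at an unadjusted p under 0.05; adjusted p = 0.000274, fewer than the rest), and 20 were higher on average after release, with a median mean of 0.25. Aminoacyl-tRNA synthetase genes gave 1 riser of 19, MES1 (1.41), and 1 adjusted over the list alone (adjusted p = 0.0408, fewer than the rest). Lists that did not pass were mitochondrial ribosomal protein genes, of which 23 of 67 fell (30 adjusted over the list alone; adjusted p = 0.314) and 55 were lower on average after release, glycosylation and secretion genes, of which 13 of 29 rose (15 adjusted over the list alone; adjusted p = 0.0799), and ergosterol genes, of which 4 of 23 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.644), with ERG5 at 1.89 and ERG24 at -0.87.

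The order of the arrays in time was tested by shuffling the 8 time labels. The real order gave 1755 time-dependent genes and was the only 1 of 100 orders to give as many, so a random order seldom gives such a count. The shuffling asks only whether arrays close in order are alike. Slide position ran in the same order as time, so it cannot tell time from position or from another smooth drift. The highest other count was 800, from an order close to the reverse of the real one, and 96 of the orders gave 0.

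Genes transcribed away from each other from a shared region may be regulated together. Over 1475 divergent neighbour pairs the fitted departures correlated at 0.259 (0.199 to 0.314), above all 1000 permutations of the genes. The correlation was -0.0147 over 1465 convergent pairs, a value that 710 of the 1000 permutations reached, and 0.077 over 2749 tandem pairs, which 1 reached; the permutations used the divergent pairs. Genes and pairs are not independent replicates, and near-identical neighbours were not removed.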
